A study of Mus musculus with 6 samples.

How the data were processed

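RNA of 6 samples of the 21EM15 line was measured, 3 with a lentiviral GFP construct and 3 with lentiviral Tdrd7 knockdown. Per the labels' protocols, RNA was extracted on spin columns with DNase treatment, checked on a Bioanalyser and turned into biotinylated cRNA for Illumina arrays. The deposited scanner table gives for each array and probe an intensity on a linear scale and a detection p-value, per the file headers. The scanner software and its settings are not given in the sources used here. The authors also deposited a processed table of intensity values with unstated processing. Each of its 6 columns was a straight line of 1 scanner column of the same group, to within 0.011 intensity units, with slopes from 0.763 to 1.29. Its column medians were 78.4 to 81.6, so its scale is linear intensity without centring by gene. The names of the scanner columns give the group and a running number from 1 to 6 but not the replicate number of the labels. The straight lines tie scanner columns 1 to 3 to control replicates 1 to 3 and columns 4 to 6 to knockdown replicates 1 to 3. Columns were assigned by name and not by their values, so the scanner values were fitted by group alone. Every column of sample values was assigned to a group. No probe had the same value on 2 arrays, so no array was a copy of another.

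The main analysis started from the scanner intensities. Background correction, quantile normalization and the log2 transform were done with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the background inferred from the detection p-values, since no negative control probes were in the table. The offset understates the fold changes of dim genes. A probe entered where its detection p was under 0.05 on all 3 arrays of at least 1 group, which 16349 of 45281 probes met. The platform annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10378. Symbols were looked up by gene identifier in a table of current symbols, which matched 34807 probes and changed 0 names. Of the probes that entered, 14107 had 1 symbol and 2242 had none or several. Each gene was represented by its probe with the highest mean, which left 9200 genes. The number of arrays limits the precision.

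Knockdown was compared with control by lmFit and eBayes of limma on all 6 arrays, with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and confidence intervals are at 95%. Gene lists were fixed before the data were examined, 26 in all, and those with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Exact permutation tests were two-sided.

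The rule for naming genes was fixed before the data were examined. It named Tdrd7, up to 15 genes in each direction with adjusted p under 0.05 and no overlap between the groups, up to 4 changed members of each changed list, and Actb, Gapdh, Hprt, Cryab, Pax6, Sparc, Hspb1 and Epha3 in any case. As 0 genes passed, the rule gave only Tdrd7 and the 8 fixed genes, and every other gene was named after its values were seen. For a gene not above background on any array of 1 group, the fold is a bound against the lowest signal detected on each array.

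The alternatives were other background corrections and normalizations, the authors' processed values, other filters, every probe by itself, the mean of a gene's probes, other variance settings, array weights and leaving out each array. The fit was tested on simulated data for this comparison, with 200 of 9200 genes changed. With independent spread per gene, 6.0% of 50 genes changed 1.5-fold were recovered, 38.0% of those changed 2-fold, 84.0% at 4-fold and 96.0% at 8-fold. With the residuals measured on the 6 arrays in its place, the shares were 0%, 16.0%, 92.0% and 100%. These residuals were centred within each group, so the fitted change equalled the planted one and the shares leave out its estimation error. Both sets of shares hold where 200 genes change, and the adjusted threshold is harder to reach where few do. In 100 simulated lists of 28 unchanged genes, camera with the preset correlation gave p under 0.05 for 62.0% when the genes shared a correlation of 0.6 and for 5.0% when they shared none. With an estimated correlation the shares were 5.0% and 1.0%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.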

Results

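Gene expression was measured in 21EM15 cells, an epithelial cell line derived from the mouse lens, with 1-colour Illumina bead arrays. There were 3 control samples, which carried a lentiviral construct with GFP. The 3 knockdown samples carried a lentiviral construct with a short hairpin RNA (shRNA) against Tdrd7. Tdrd7 encodes a Tudor domain protein of cytoplasmic RNA granules, and its loss is known to lead to cataract. The arrays held 45281 probes, of which 37.2% to 38.8% were detected on each array. The median probe signal per array lay between 72.6 and 82.6 intensity units. Arrays are numbered as in the scanner table, 1 to 3 for control and 4 to 6 for knockdown. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

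The comparison asks which transcripts differ between the knockdown and control samples of these lens epithelial cells. The labels name no shRNA for the control samples. Effects of the constructs themselves therefore cannot be told apart from those of reduced Tdrd7. Tdrd7 itself was lower on all 3 knockdown arrays. The signal of its only probe on the array was 854 ± 50.6 in control and 285 ± 29.7 in knockdown (mean ± SD, n = 3). The 3 control arrays gave 854, 804 and 905, and the 3 knockdown arrays gave 295, 252 and 308. After normalization the log2 fold change was -1.85 ± 0.28 (SE), with a 95% confidence interval from -2.50 to -1.20. This is 3.61-fold lower, with 27.7% of the control level remaining. Among the 9200 genes tested, it was the largest fitted decrease. The limma p-value for this gene alone, without correction for the other genes, was 1.7e-04, and adjusted over all 9200 genes it was 0.76. A two-sided exact permutation test gave p = 0.1, the smallest value that 3 arrays against 3 allow.

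**Figure D1:**
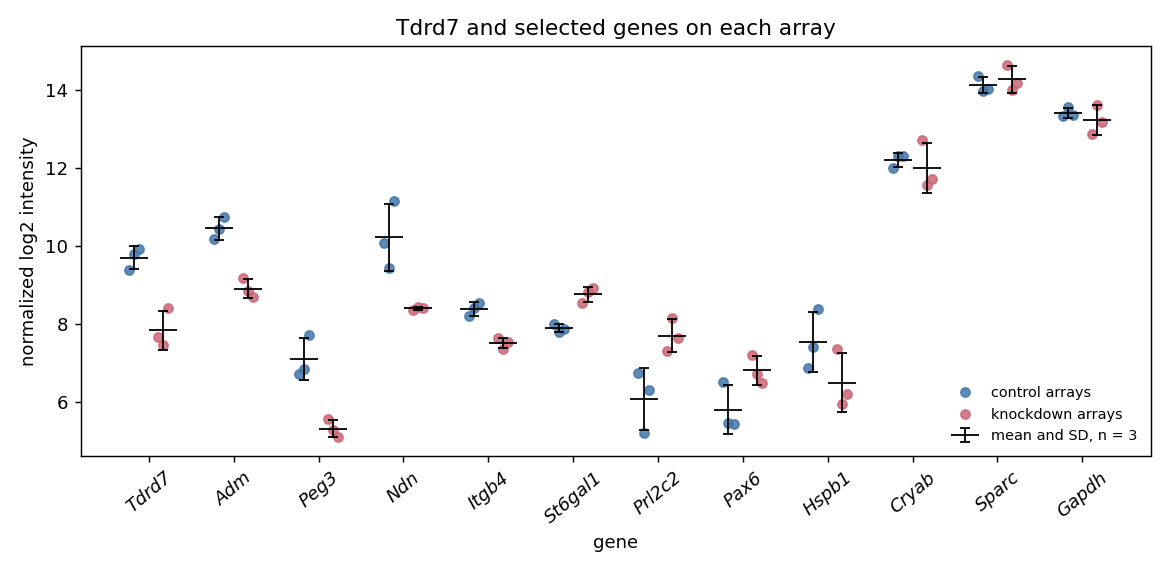
Normalized log2 intensity (vertical axis) of 12 genes on each array, with points for the 3 control and 3 knockdown arrays and bars for the mean and SD. The 3 knockdown arrays lie below the 3 control arrays for Tdrd7, Adm, Peg3, Ndn and Itgb4 and above them for St6gal1 and Prl2c2, and the groups overlap for Pax6, Hspb1, Cryab, Sparc and Gapdh.

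No gene passed an adjusted p of 0.05 in the limma fit of knockdown against control, and the lowest adjusted p was 0.76. At an unadjusted p under 0.05 there were 303 genes, 131 higher and 172 lower in knockdown, where chance alone would give 460. The knockdown arrays lay entirely above or below the control arrays for 720 genes, 7.83% of those tested, where chance gives 10%. The fitted change reached 2-fold for 15 genes in the upward direction and 31 in the downward direction, without any of them passing the test. The median gene had a 95% confidence interval of ± 0.50 log2 units, a 1.42-fold change either way.

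**Figure D2:**
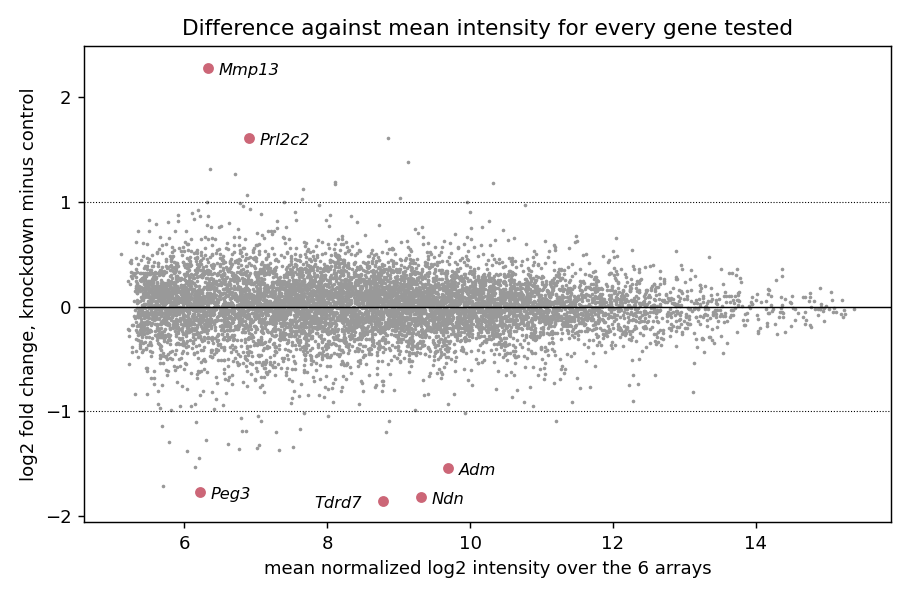
Log2 fold change, knockdown minus control (vertical axis), against the mean normalized log2 intensity over the 6 arrays (horizontal axis) for each of the 9200 genes tested, with dotted lines at 2-fold. Tdrd7, at -1.85, is the lowest point, and Mmp13, at 2.28, is the highest, although Mmp13 was detected on only 1 of the 3 control arrays.

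Because no gene met the rule fixed for naming genes, the genes in this paragraph were chosen after their values were seen, as a selection from those with large differences and no overlap between groups, together with Cdkn1c and G3bp1, which also showed no overlap. None passed the limma test, where their adjusted p-values lay between 0.76 and 1.00. Below control were the transcript of the hormone adrenomedullin, Adm, at -1.54 ± 0.22 log2 units (SE), and those of the imprinted genes Peg3 at -1.77 ± 0.28 and Ndn at -1.82 ± 0.39. Cdkn1c, an imprinted gene for a cell cycle inhibitor, was at -0.84 ± 0.19. The lysosomal protease gene Ctsl was at -1.35 ± 0.36, and the endocytic receptor gene Lrp2 at -1.19 ± 0.29. G3bp1, which encodes a core protein of stress granules, was at -0.78 ± 0.20. Peg3 was detected on 1 of the 3 knockdown arrays, so its value is set against a level close to background. Aard was not well above background on any knockdown array and was at least 2.41-fold lower there, taking the lowest signal detected on each array as the floor. Above control were the collagenase gene Mmp13 at 2.28 ± 0.97 and the matrix protein genes Postn at 1.12 ± 0.39 and Efemp1 at 1.00 ± 0.31. The iron exporter gene Slc40a1 was at 0.97 ± 0.27, and the sialyltransferase gene St6gal1 at 0.86 ± 0.18. Prl2c2, of the proliferin family, was at 1.61 ± 0.40, and its near-identical relatives Prl2c4 at 1.32 ± 0.35 and Prl2c3 at 1.26 ± 0.30 may share signal with it. Prl2c2 and Prl2c4 were detected on 2 of the 3 control arrays, and Mmp13 on 1 of them, so part of their control values was not above background. The Mmp13 value rests mainly on knockdown array 4, where it was 10.12 log2 units against 5.71 and 6.57 on arrays 5 and 6.

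Of the 17 gene lists with at least 5 tested members, 4 passed an adjusted p of 0.05 in the limma camera test with its preset correlation. Cell cycle genes were lower, with 26 of 28 tested members below control, a mean log2 fold change of -0.36 and an adjusted p of 2.36e-05. Cholesterol synthesis genes were lower too, with 16 of 18 members below control, a mean of -0.38 and an adjusted p of 2.36e-05. Interferon-stimulated genes had 26 of 31 members below control, a mean of -0.37 and an adjusted p of 7.8e-04. Genes of epithelial-mesenchymal transition (EMT) and fibrosis had 22 of 27 members above control, a mean of 0.30 and an adjusted p of 0.0046. All 4 calls were lost when camera estimated the correlation within each list, with an adjusted p of 0.97 for each. The estimates were 0.80 for cell cycle, 0.66 for cholesterol synthesis, 0.62 for interferon-stimulated and 0.23 for EMT and fibrosis genes. The preset of 0.01 lies far below them, so the preset p-values overstate the evidence for these lists. Exact permutation tests of the list means gave p = 0.6, 0.4, 0.5 and 0.4 in the same order. No member of these 4 lists passed the limma test over all genes, and 0 passed adjusted over the list alone. The members with the largest differences, chosen after they were seen, were Mcm3 (-1.06 ± 0.51, SE) and Mcm5 (-0.78 ± 0.70) of the replication helicase. For cholesterol they were the mevalonate kinase gene Mvk (-0.82 ± 0.30) and Cyp51 (-0.77 ± 0.38). For interferon they were Isg15 (-0.87 ± 0.67) and Dhx58 (-0.81 ± 0.42), and for EMT and fibrosis the collagen genes Col3a1 (1.61 ± 0.61) and Col5a2 (1.19 ± 0.42). The groups overlapped for each of these 8 genes, and Mcm3 was detected on 2 of the 3 knockdown arrays.

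The 3 knockdown arrays did not move alike in these lists. On array 4 all 28 cell cycle genes lay below their mean over the 6 arrays, by 0.96 log2 units on average (mean deviation -0.96), while on array 5 all 28 lay above it (0.66), and array 6 was at -0.25. Cholesterol synthesis genes were at -0.86 on array 4 and at 0.16 and 0.13 on arrays 5 and 6. EMT and fibrosis genes were at 0.54 on array 4, and at -0.18 and 0.08 on the others. Reference genes lay on the same side as the cell cycle genes on arrays 4 and 5, at -0.33 on array 4, with 10 of 12 members below their mean, and at 0.26 on array 5. Tfrc, the member with the largest deviation, was at -2.37 on array 4. Without array 4, a choice made after seeing the data, the mean log2 fold change was 0.024 for cell cycle genes, -0.043 for cholesterol synthesis genes and 0.10 for EMT and fibrosis genes, and none of the 3 lists passed camera. The EMT and fibrosis call was also lost without control array 2 (mean 0.19). Without knockdown array 5 the 3 means were larger in size, at -0.79 for cell cycle, -0.55 for cholesterol synthesis and 0.46 for EMT and fibrosis genes. Interferon-stimulated genes varied within both groups: they were at 0.84 on control array 3 and 0.45 on knockdown array 6, against -0.83 on knockdown array 5. Without control array 3 their mean log2 fold change was -0.04, and without knockdown array 5 it was -0.04 as well, with the camera call lost in both. It was larger in size without control array 1 (-0.56), control array 2 (-0.50) or knockdown array 6 (-0.68). Array 4 also stood apart over all genes, with a mean correlation of 0.957 with the other arrays, where the others had 0.971 to 0.976.

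**Figure D3:**
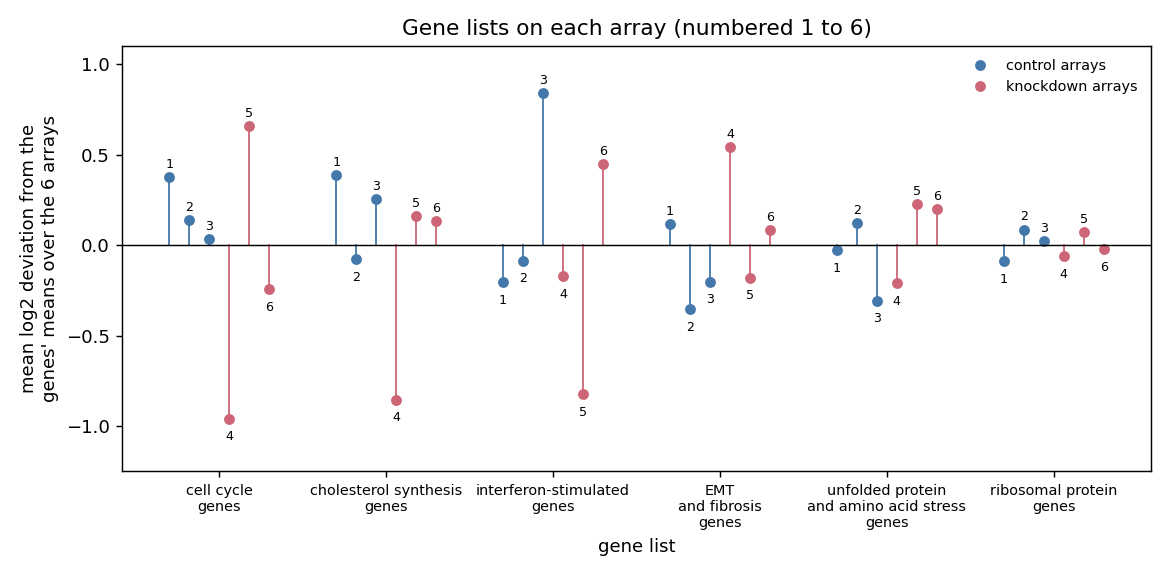
Mean log2 deviation of the tested members of 6 gene lists from their means over the 6 arrays (vertical axis), with 1 point per array, coloured by group and numbered as in the scanner table. Array 4 holds the lowest cell cycle (-0.96) and cholesterol synthesis (-0.86) values, whereas ribosomal protein genes lie between -0.091 and 0.086 on the 6 arrays.

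The other lists fixed before the data were examined did not pass the camera test. P-body and stress granule genes, which encode components of RNA granules, had 24 of 38 members above and 14 below control, with a mean log2 fold change of 0.01 and an adjusted p of 0.96. Genes of lens epithelium and eye development had 8 of 14 members above control (mean 0.10, adjusted p = 0.49). Heat shock proteins and chaperones had 13 of 21 above control (mean 0.03, adjusted p = 0.70), and Eph receptors and ephrins 6 of 9 (mean 0.05, adjusted p = 0.86). Genes linked to glaucoma had 4 of 7 above control (mean 0.17, adjusted p = 0.43). Basement membrane and lens capsule genes had 16 of 21 above control (mean 0.10, adjusted p = 0.43), although Itgb4, an integrin subunit of epithelial cells, was at -0.86 ± 0.18 log2 units (SE). Itgb4 passed adjusted over the list alone (limma adjusted p = 0.027), as did Adm among glycolysis and hypoxia genes (adjusted p = 0.0021). They and Ramp2, an endothelial marker at -0.71 ± 0.20 (limma, adjusted p = 0.030, adjusted over the list alone), were the only 3 such members of the 26 lists. None of them passed over all genes.

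Single lens genes fixed before the data were examined showed no difference past the limma threshold. Pax6, the transcription factor of eye development, was at 1.00 ± 0.33 log2 units (SE, interval 0.24 to 1.77), with the highest control array at 6.53 and the lowest knockdown array at 6.51. The small heat shock protein gene Hspb1 was at -1.05 ± 0.46 (interval -2.12 to 0.02). The crystallin gene Cryab was at -0.21 ± 0.31, the matrix protein gene Sparc at 0.15 ± 0.22 and the Eph receptor gene Epha3 at -0.03 ± 0.20. Epha3, with means of 5.64 in control and 5.62 in knockdown, lay close to the lowest signal detected per array, 5.23 to 5.34 log2 units. Its small value therefore cannot show that it is unchanged. Pax6 was close to that level too on control arrays 2 and 3, at 5.47 and 5.45. Of the 16 crystallin genes on the array, 3 were detected well enough to be tested, and of 15 lens fibre genes, 2 were. The reference genes Actb (-0.05 ± 0.20), Gapdh (-0.19 ± 0.23) and Hprt (0.16 ± 0.25) differed by less than their intervals. The Actb value is that of its brightest probe. Its 5 probes ranged from -0.76 to 6.9e-04, and with the mean of a gene's probes Actb was at -0.34. The sign for Actb turned when arrays were weighted or array 4 was left out (0.04 and 0.09), while it, Gapdh and Hprt kept their signs under each scaling of the arrays.

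When every probe was fitted by itself, 1 of the 16349 probes that were detected passed an adjusted p of 0.05 in limma (5.06e-06). This probe, ILMN_2476405, has no gene name in the annotation used here and so did not enter the gene counts. It was chosen for mention after its values were seen. Its signal was 7674 ± 576 on the control arrays and 97.0 ± 7.56 on the knockdown arrays (mean ± SD, n = 3), and on knockdown array 5 it was not above the detection limit. As the knockdown signal lay close to background, the size of the fold depends on the background correction: the log2 difference was -7.55 in this fit and lay between -7.55 and -6.30 over the normalizations tried.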

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

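Tdrd7 stayed lower and short of the adjusted threshold under all 19 alternatives that gave it a value, with log2 fold changes from -2.14 to -1.62 and limma adjusted p from 0.13 to 1.00. The count of changed genes was 0 under 18 of the 19 alternatives. It was 1, lower in knockdown and over 2-fold, when every probe was fitted by itself, because unnamed probes then enter. Leaving out each array in turn gave 0 changed genes each time. At an unadjusted p under 0.05 there were 303 genes, 98 without normalization between arrays, 782 without a filter, 528 for every probe by itself and 814 with array weights. That count was 107 without control array 3 and 462 without knockdown array 5. The cause was not tested, beyond the larger number of probes or genes in the unfiltered and single-probe fits.

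The number of lists past the threshold was 4, and 0 with estimated correlation or with fry, where the lowest adjusted p was 0.89. Leaving out 1 array gave 2 to 5 lists, with 2 without knockdown array 4: interferon-stimulated genes, and genes of unfolded protein and amino acid stress (mean 0.28, adjusted p = 0.0030, but 0.97 with an estimated correlation), which also passed with array weights (0.35) and without control array 2 (0.24). EMT and fibrosis genes narrowly missed the threshold with array weights (0.23, adjusted p = 0.051). The list of p53 targets passed only without control array 2 (mean 0.38), and basement membrane genes only without knockdown array 5 (0.23). The lists were not run on single probes.

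No value had a call under the alternative that turned its sign. Cell cycle genes had one with all arrays, and their mean ranged from -0.79 without knockdown array 5 to 0.024 without array 4. Leaving out each array in turn, the list means ranged from -0.014 to 0.20 for lens epithelium, -0.029 to 0.083 for heat shock, -0.027 to 0.069 for P-body and stress granule, -0.0086 to 0.23 for basement membrane, -0.0028 to 0.072 for Eph, -0.023 to 0.045 for oxidative stress, -0.096 to 0.20 for TGF-beta and BMP, -0.16 to 0.14 for reference and -0.058 to 0.030 for ribosomal protein genes. In these same fits the log2 fold changes ranged from -0.18 to 0.089 for Actb, -0.057 to 0.33 for Hprt and -0.57 to 0.012 for Cryab. They ranged from -0.034 to 0.30 for Sparc, -0.15 to 0.095 for Epha3, -1.50 to 0.12 for Mcm5 and -1.17 to 0.066 for Tyms. Reference genes were at 0.0024 with 75th percentile scaling and 0.020 without normalization between arrays, where ribosomal protein genes were at 0.011. Array weights put Actb at 0.042 and reference genes at 0.051. Eph genes were at -0.012 without a filter, and TGF-beta and BMP genes at -0.00504 with the mean of a gene's probes. With the authors' processed values, P-body genes were at -0.015 and oxidative stress genes at -0.015. The cause was not tested. All other genes named kept their direction.

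The replicate block was fitted on the authors' processed values, a pair of choices joined after seeing the data, since the names of the scanner columns carry no replicate number. It was not fitted on the scanner values. With the replicate block 0 genes changed, Tdrd7 was at -1.63 (adjusted p = 0.98) and 4 lists passed, while P-body genes were at -0.015 and oxidative stress genes at -0.015. Deviations of same-numbered samples correlated at -0.10, 0.13 and 0.59, and only for number 3 did the control sample correlate best with its own number. Not all 3 lay above 0.1, so the numbers were not taken to pair the samples, but these values do not exclude a pairing. Immediate early genes, a list chosen after seeing the data, had like values in samples of the same number. On the authors' values, 257 genes had an unadjusted limma p under 0.05 without the block and 432 with it. Slide could not be fitted as a block because the files give no slide, and Tdrd7 has no second probe to compare.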

Other observations

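The tests that leave out array 4, those of the unnamed probe, of the imprinted genes and of the splits for changed genes were chosen after the result was seen, as were the lists of immediate early and imprinted genes. Immediate early genes, which respond within minutes to serum or handling, varied more between arrays of 1 group than between groups. The 14 tested members were at a mean log2 deviation of 0.96, 0.19 and -1.20 on control arrays 1, 2 and 3 and of 0.85, 0.14 and -0.94 on knockdown arrays 4, 5 and 6. Arrays 1 and 4, 2 and 5, and 3 and 6, which hold samples of the same replicate number by the match to the authors' table, thus had like values for this list. Fos, the best known of them, was at -2.32 on array 3 and -2.57 on array 6 and between 0.92 and 1.58 on the other 4. Of the 5 Actb probes, 2 dim ones also parted the arrays without regard to group: ILMN_2846865 read 413, 329 and 411 on arrays 1, 4 and 5 and 948, 941 and 801 on arrays 2, 3 and 6.

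Other lists fixed before the data were examined did not pass camera. Genes of p53 response had 12 of 19 members above control (mean 0.15, adjusted p = 0.43), those of unfolded protein and amino acid stress 19 of 27 (mean 0.14, adjusted p = 0.43) and those of TGF-beta and BMP response 11 of 15 (mean 0.04, adjusted p = 0.96). Glycolysis and hypoxia genes had 11 of 19 below control (mean -0.07, adjusted p = 0.49), ribosomal protein genes 29 of 49 (mean -0.01, adjusted p = 0.77) and reference genes 8 of 12 (mean -0.02, adjusted p = 0.83). Oxidative stress and metal response genes had 14 of 27 below control, with a median of -0.06 but a mean of 0.02 (adjusted p = 0.97). In 9 lists fewer than 5 genes were detected and no test was run. All 3 germ granule and piRNA pathway genes tested were below control (mean -0.19). Without knockdown array 4, 1 of them was above and 2 were below control (mean -0.093). Their mean deviation was -0.30, 0.14 and -0.13 on knockdown arrays 4, 5 and 6. Crystallins (3 tested) were at 0.05 and lens fibre genes (2 tested) at -0.32. Markers of immune cells (3 tested) were at -0.23, endothelium (4) at -0.23, muscle and pericytes (3) at 0.24, surface epithelium and cornea (3) at 0.11, and neurons, retina and glia (2) at 0.01. No marker of pigment cells was tested.

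With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 changed genes, and the highest of the other splits also 0, so this count cannot tell the real split from the others. For gene lists past the preset camera threshold the real split gave 4 and the highest of the others 8, and 7 of the 10 splits gave at least 4. At an unadjusted p under 0.05 the real split gave 303 genes, and 7 other splits gave more, up to 1196 for arrays 1, 3 and 6 against 2, 4 and 5. That split follows no label and was picked as the highest after the counts were seen. Apart from the correlations and the block by replicate number given above, whether the samples have a structure other than their group was not tested.

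Without knockdown array 4 the mean log2 fold changes were 0.024 for cell cycle, -0.043 for cholesterol synthesis and 0.10 for EMT and fibrosis genes. These 3 list calls thus depended on array 4. It was left out after it was seen to hold the most extreme values of these lists, so smaller means were bound to follow. Whether array 4 is the odd array cannot be told from this. Without knockdown array 5 the means were larger in size, at -0.79, -0.55 and 0.46, and all 3 lists passed camera. The EMT and fibrosis call was also lost without control array 2 (0.19, camera adjusted p = 0.10) and with array weights (0.23, camera adjusted p = 0.051). The interferon-stimulated list does not rest on array 4 (-0.37 without it) but on other single arrays, as its mean was -0.037 without control array 3 (adjusted p = 0.87) and -0.045 without knockdown array 5 (adjusted p = 0.97). For the low cell cycle genes of array 4, the choice of normalization is argued against, because their mean deviation was at most -0.71 under each of the other normalizations. RNA from other cell types stays open, as 2 of the 76 marker genes of other types were detected on array 4 alone, with 1 each on control arrays 1 and 3 alone, and the tested markers there were at mean deviations from -0.28 (endothelium) to 0.44 (muscle and pericytes). No biological explanation was tested.

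The unnamed probe ILMN_2476405 was bright on all 3 control arrays and near background on all 3 knockdown arrays. A defective array is argued against, since the log2 difference was still -7.45 or larger in size whichever array was left out. As the knockdown signal is close to background, the exact size depends on the processing and lay between -7.55 and -6.30 over the normalizations. A candidate explanation is that the probe reads a sequence carried by the control construct. This hypothesis cannot be told apart from a mouse transcript lost in knockdown, because a signal that falls to near background (-7.55 in the fit) would be seen with both and the probe's sequence was not used here.

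Peg3, Ndn and Cdkn1c are imprinted genes and were each lower on all 3 knockdown arrays, which prompted the hypothesis that imprinted genes are lower as a set. The 19 other imprinted genes tested had 11 members below control, a mean log2 fold change of -0.03 and a limma camera p of 0.44. They gave no sign of a shift of the set beyond the 3 genes that prompted it.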
